A study of Oryza sativa Japonica Group with 36 samples.

How the data were processed

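Small RNA was measured in 32 libraries and cleaved RNA ends in 4 PARE libraries of rice. Per the labels, RNA was taken with TRIzol, small RNA libraries were made with the TruSeq Small RNA kit, and Bowtie is named without a version or a stated role. The deposited files list each tag of 18 to 34 nt with its counts, and these counts are the unit of every file used, with adapter trimming and filters not stated in the labels. A check of the files found whole numbers in all of them. Groups were taken from the sample titles. The title, source and description of 2 PARE libraries say short day while another field says long day, and the title was used. The depth was 6299626 to 29509417 reads per small RNA library of the lines (median 10123284.5), 17293190 to 24179355 per transgenic library and 34120199 to 42420515 per PARE library.

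Library size was the number of 18 to 30 nt reads, with no further scaling, because a scaling that centres the tested features would take out a change shared by a whole class. No genome was used, so tags stand for the PHAS loci that the design names: 21-nt and 24-nt tags with at least 10 reads in at least 2 libraries were kept and then filtered by edgeR's filterByExpr, which left 31333 of 36669 21-nt tags and 101210 of 147876 24-nt tags in the lines and 36098 of 38905 21-nt tags in the transgenic libraries. The tags that met the minimum cover 79.5% of 21-nt reads and 37.6% of 24-nt reads in the lines. Shares of ribosomal, transfer and chloroplast RNA, a restriction to 1 chromosome, a phase score along a genome and the sharing of tags between genome matches were not run.

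Phased contigs were added after the data were examined. The tags assembled included those of the PARE libraries. With k-mers of 17 nt they gave 43739 21-nt and 47718 24-nt contigs, of which 4908 and 19206 had at least 200 reads. A contig was called phased when, in a window of 10 cycles, at least 4 cycles held reads, at least 50% of reads were in 1 register and the top tag held under 80%, counted in the 24 libraries of the lines. This gave 191 contigs at 21 nt (median length 318 nt, 4.73% of reads) and 39 at 24 nt (389 nt, 1.62%). Wrong cycle lengths called 0 to 2 and 1 to 3 contigs. The thresholds differ from the phase score and hypergeometric rule fixed in the design, which needs a genome. At least 13 parameter settings were tried, and the assembly was widened to all 32 small RNA libraries because the PMS1T candidate was lost without the transgene-positive ones. Tested on simulated data, 100 phased loci gave 126 contigs, of which 58 were called, and 0 of 101 unphased contigs were called. The PMS1T candidate was found by ranking contigs by their rise in RNAi-positive plants, with a floor of 0.5 RPM in the lines. Its register shares carry 95% Clopper-Pearson intervals.

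Known miRNAs were matched by sequence from a hand-written list of 39 miRNAs and small RNA families, of which 30 were tested in the lines and 31 in the transgenic libraries, and an abundant miR529 variant was added later. The lists fixed before the data were examined were phasiRNA triggers (4 listed, 4 tested), phase change and flowering (5, 3), anther and floral development (16, 15), nutrient and stress (11, 5), small RNA machinery (2, 2) and monocot MADS-box regulator (1, 1).

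Counts were fitted with edgeR 4.0.16 in R 4.3.3, a model of group means with the quasi-likelihood test and Benjamini-Hochberg adjustment over all features of a class, at an adjusted p of 0.05. The comparisons were long against short days in each line, over the 3 stages and at each stage, genotype by daylength, 58S against NIL(MH) under long days, 1.0 to 2.0 cm against 0.5 to 1.0 cm panicles, florets against 1.0 to 2.0 cm panicles, and transgene-positive against transgene-negative plants. The comparisons of 58S with NIL(MH) under short days in contigs and tags, of the 58S daylength change between stages, of genotype by daylength at 0.5 to 1.0 cm and of stages within NIL(MH) short days were added after the data were examined. Summed tags were compared by two-sided exact permutation within stages (over all regroupings, smallest p 0.009259). The names printed follow a rule fixed before: miRNAs past the adjusted p, miR2118 and miR2275 always, and per comparison up to 10 rises and 10 falls among tags or contigs past the adjusted p with a mean of at least 5 RPM and groups that do not overlap within each stage. Named tags of the transgenic comparisons also had to meet the minimum count in the lines and not start with adapter sequence, a limit added later. Among those, features with a call that held when single libraries were left out were preferred, a choice made after the fits. The correlation of miRNA changes with panicle size had no prediction written beforehand, and the NIL libraries that stood apart were chosen from their differences to their replicates. A tag with no read in 1 group is given as a lower bound from a floor of 3 counts over that group.

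Target sites for miR2118 and miR2275 were searched in the phased contigs with a penalty of at most 5, and PARE 5′ ends were counted within 1 nt of the cleavage position with 95% exact intervals. The search used the 10 most abundant tags of each family. The test of seed-only sites was added after the data were examined.

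The alternatives were TMM scaling, DESeq2 1.42.0 with its own size factors, reads of 20 to 24 nt as library size, no low-count filter, the replicate number as a block, each library left out in turn, a target penalty of at most 4 and the exact cleavage position. Added later were TMM factors from 24-nt tags, both alleles of the PMS1T candidate counted, 2 NIL libraries left out that stood apart from their replicates, contigs at least 70% in phase, in-phase tags only, tags shared between contigs, and phased contigs in place of tags. On simulated data the fit recovered 6% of 2-fold and 60% of 4-fold changes of 21-nt tags in 58S by daylength and 7% and 45% of 24-nt tags, with 4.3% and 0% false calls. It recovered 24% and 75% in overexpressors and 0% and 0% for 2 libraries against 2 at 1 stage of the lines, a size at which changes shared by a whole class were still called in the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 was used for the other steps.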

Results

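Small RNA was sequenced from young inflorescences of Nongken 58S (58S), a rice line that is male sterile when days are long and fertile when days are short, and of NIL(MH), the near-isogenic line the series sets beside it. Both lines grew in the field under long days, with over 14 h of light, and under short days, with under 13.5 h. Long against short days thus compares field conditions, and whatever else differed between them cannot be told apart from daylength. Panicles of 0.5 to 1.0 cm, panicles of 1.0 to 2.0 cm and florets of 3.0 to 4.0 mm were taken, with 2 libraries in each of the 12 groups. A further 8 libraries came from long-day panicles of 1.0 to 2.0 cm of plants that overexpress PMS1T, a long noncoding RNA of a fertility locus that is cut into phased small RNAs, of PMS1T RNAi plants, and of the transgene-negative plants of each kind, with 2 libraries per group. The other 4 libraries were PARE libraries, which read the 5′ ends of cleaved RNA, with 1 library for each line and daylength at the 1.0 to 2.0 cm stage. The 24 small RNA libraries of the lines held 6299626 to 29509417 reads each, the transgenic libraries 17293190 to 24179355, and the PARE libraries 34120199 to 42420515. Reads of 21 nt made up 10.6% to 33.0% of the 18 to 30 nt reads in the libraries of the lines, and reads of 24 nt made up 36.2% to 55.9%.

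The features compared were known miRNAs, single 21-nt and 24-nt tags, and contigs assembled from the tags that hold a window of reads in 21-nt or 24-nt register, the mark of phased small interfering RNAs (phasiRNAs) that grass anthers make in large amounts. There were 191 phased 21-nt contigs and 39 phased 24-nt contigs, named here by length class and number, and no position on a chromosome is given because no genome was used. Over whole contigs the median share of reads in phase was 90.7% at 21 nt and 58.1% at 24 nt, so many 24-nt contigs hold mostly or partly reads out of phase. NIL long-day replicate 1 of panicles of 1.0 to 2.0 cm and of florets stood apart from their replicates, and counts without both are given where they move a result. Abundance is in RPM, reads scaled to 1000000 reads of 18 to 30 nt, values are means ± SD over libraries, and changes are log2 values ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. These p-values measure spread between these samples, and every interval or floor given covers counting error only, because PCR copies are not independent molecules.

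The first question was whether daylength changes small RNAs in the sterile line, and at which stage. In 58S panicles of 0.5 to 1.0 cm, phased 21-nt small RNAs were scarcer under long days: the contigs summed to 2889.6 ± 805 RPM, against 6339 ± 1479 under short days (n = 2 each). At that stage 186 of the 191 phased 21-nt contigs fell and 0 rose (186 at an unadjusted p under 0.05), with a median change of −2.31 and quartiles of −2.67 and −2.04. The contigs moved together and are not independent replicates. For 2 libraries against 2, an exact permutation test cannot fall below a two-sided p of 0.333. The contigs with the most reads, PHAS21-001 and PHAS21-002, did not fall (0.05 and 0.27, adjusted p = 0.848 and 0.323). PHAS21-096 fell from 12.1 ± 5.38 to 0.955 ± 0.768 RPM (−3.55 ± 0.53, adjusted p = 2.85e-06) and PHAS21-124 fell as well (−3.24 ± 0.47, adjusted p = 2.64e-06). In panicles of 1.0 to 2.0 cm the contigs summed to 9807 ± 295 RPM under long days and 10891 ± 325 under short days, and in florets to 17367 ± 709.9 and 16415 ± 1127. None of these contigs changed at either later stage by edgeR (1 and 2 at an unadjusted p under 0.05; 0 at both by DESeq2). The daylength change itself differed between stages, being lower at 0.5 to 1.0 cm than at 1.0 to 2.0 cm in 177 contigs and lower than in florets in 183, with library size as the only scaling. Without 58S long-day 0.5 to 1.0 cm replicate 1, the change at the first stage was −4.86 for PHAS21-096 and −4.04 for PHAS21-124. TMM scaling or DESeq2 over the contigs alone sets their common change to near 0 by construction, and then 7 contigs rose and 3 fell (TMM) or 9 rose and 4 fell (DESeq2). The stage contrasts of the daylength change turned likewise, to 2 and 4 contigs higher and 0 lower under TMM and to 4 and 5 higher and 0 lower by DESeq2.

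**Figure D1:**
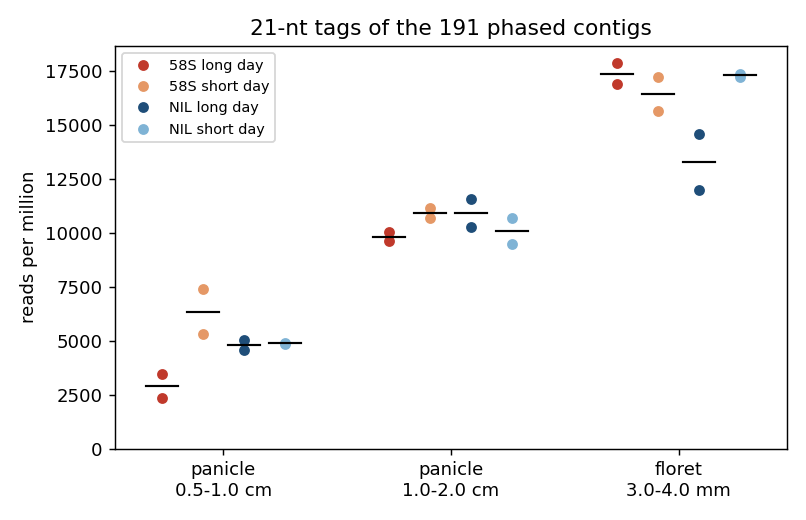
Summed abundance of 21-nt tags of the phased 21-nt contigs (RPM) in each library of 58S and NIL(MH), by stage and daylength; points are libraries and bars are means of 2. At 0.5 to 1.0 cm both 58S long-day libraries lie below both short-day libraries.

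Single 21-nt tags at the 0.5 to 1.0 cm stage of 58S changed the same way. Of 31333 tags tested, 58 rose and 12569 fell, with a median over all tags of −2.14, while the median 24-nt tag stood at 0.02. GCATTAGGAGATTGTTGGCCT fell from 12.5 ± 9.46 to 0.493 ± 0.405 RPM (−4.55 ± 0.71, adjusted p = 0.00137). The count was 2079 without 58S long-day 0.5 to 1.0 cm replicate 2 and 1771 without short-day replicate 2 of that stage. The direction turned with the scaling: TMM over the same tags gave 824 rises and 184 falls, and DESeq2 2371 rises and 166 falls, since both set the common change to near 0. TMM factors taken from the 24-nt tags gave 34 rises and 14004 falls. At 1.0 to 2.0 cm 0 tags changed (495 at an unadjusted p under 0.05; DESeq2 called 0 rises and 2 falls). In florets 1 tag rose, AGAGTTGGATGAAAGCAAACT (adjusted p = 0.0396), a call that ended without any 1 of the 4 libraries, each of which left a count of 0 (12 rises and 3 falls by DESeq2, 8 and 1 without the 2 NIL libraries that stood apart).

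**Figure D2:**
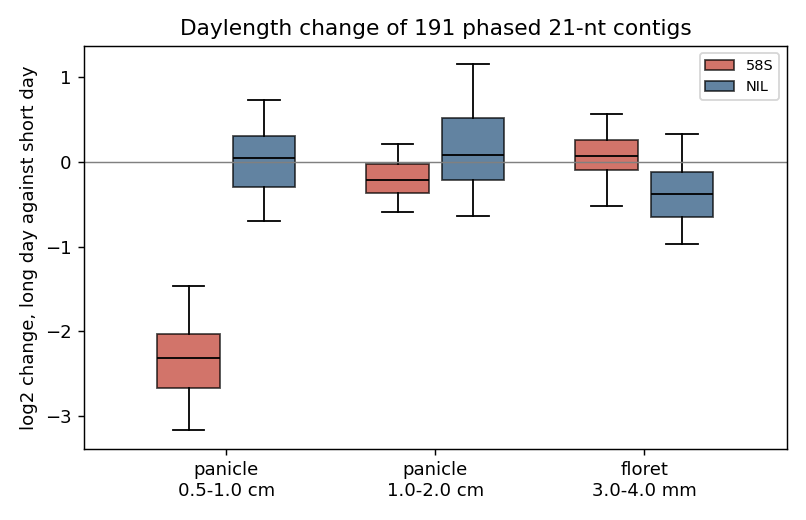
Log2 change of the 191 phased 21-nt contigs for long against short days, by line and stage (boxes are quartiles, whiskers the 5th to 95th percentiles). The box of 58S panicles of 0.5 to 1.0 cm lies lowest, around a median of −2.31; scaling over the contigs alone moves that median to near 0.

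The miRNA families that start phasiRNA production went down at the same stage. In 58S panicles of 0.5 to 1.0 cm, the miR2118 family, which triggers 21-nt phasiRNAs, fell from 666.2 ± 206 to 222.8 ± 109 RPM (−1.58 ± 0.36, adjusted p = 0.00594). The miR2275 family, which triggers 24-nt phasiRNAs, had 1 read against 15 there, a ratio of 0.0659 with a 95% exact interval of 0.00157 to 0.428 (adjusted p = 0.0219). miR156, which holds plants in the juvenile phase, rose from 8.71 ± 1.70 to 26.6 ± 2.03 RPM (1.62, adjusted p = 0.0225). These were the miRNAs called at this stage, and each depends on single libraries. Without 58S long-day 0.5 to 1.0 cm replicate 1, the adjusted p was 0.536 for miR2275 and 0.22 for miR156, and miR2118 stood at −2.19. Without long-day replicate 2, it was 0.0762 for both miR2118 and miR156, and miR2275 stood at −5.65. Without short-day replicate 1 it was 0.0734 for miR156. Without short-day replicate 2 it was 0.194 for miR2118, 0.281 for miR2275 and 0.281 for miR156. The miR156 call also ended under DESeq2 (adjusted p = 0.0914), TMM (0.283) and TMM factors from 24-nt tags (0.0511). The daylength change at this stage minus that in florets was −1.70 for miR2118, −3.57 for miR2275 and 2.23 for miR156 (adjusted p = 0.0288 each). Leaving out 1 of the 8 libraries ended the miR156 call every time and the other calls in 6 cases each, at adjusted p of 0.0571 to 0.631. In the list of phasiRNA triggers, fixed before the data were examined, 2 of 4 fell, adjusted over the list alone and over all 30 miRNAs alike, and in the phase change and flowering list 1 of 3 rose on both counts.

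At 1.0 to 2.0 cm, 58S long-day panicles held more of 3 nutrient and stress miRNAs and less miR2275. miR398b, which acts on copper-zinc superoxide dismutase, rose by 2.49 (adjusted p = 0.0035), miR528 by 2.06 (0.0035) and miR408-3p by 2.17 (0.00541). miR2275 had 11 reads under long days and 68 under short days, a ratio of 0.189 with a 95% exact interval of 0.0899 to 0.359 (adjusted p = 0.00541). In 58S florets, where most of its reads lie, miR2275 had 1611 reads under long and 2200 under short days, a ratio of 1.10 (95% exact interval 1.03 to 1.17), and did not change by edgeR (0.07, adjusted p = 0.986). Without 58S long-day 1.0 to 2.0 cm replicate 2 the adjusted p became 0.141 for miR398b, miR528 and miR2275 and 0.326 for miR408-3p. Without short-day replicate 2 it became 0.0806 for miR398b and miR528, 0.128 for miR408-3p and 0.119 for miR2275. The nutrient and stress list had 4 rises adjusted over the list alone and 3 over all miRNAs at this stage, and 1 and 0 in florets.

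Averaged over the 3 stages, most phased 21-nt contigs of 58S were lower under long days, and 3 of the 5 nutrient and stress miRNAs tested, miR398b, miR528 and miR408-3p, were higher. Of the 191 contigs, 166 fell and 0 rose (168 at an unadjusted p under 0.05), with a median of −0.83. Of 100 regroupings of the libraries within stages, the real one included, 22 gave as many calls. By stage the median ran from −2.31 in the youngest panicles through −0.21 to 0.07 in florets. PHAS21-143 fell to 8.95 ± 7.86 RPM (n = 6 libraries per daylength; −1.54 ± 0.27, adjusted p = 0.000122). Under scaling over the contigs alone the direction was mixed, with 8 rises and 4 falls by TMM and 8 rises and 6 falls by DESeq2, and PHAS21-143 stood at −0.74 under both. miR398b rose by 1.42 ± 0.32 (adjusted p = 0.00275) and miR2275 fell by 1.91 ± 0.40 (adjusted p = 0.00239), which became −2.63 without 58S long-day 0.5 to 1.0 cm replicate 2. miR528, which targets genes of copper proteins, rose (adjusted p = 0.00576), but not without 58S long-day floret replicate 1 (0.0614). miR408-3p rose by 1.18 (adjusted p = 0.00728), but not without 58S long-day floret replicate 1 (0.0671), long-day 1.0 to 2.0 cm replicate 2 (0.0716) or short-day 1.0 to 2.0 cm replicate 2 (0.0511). miR166a, which sets leaf and floral polarity, rose by 0.66 (adjusted p = 0.0401). That call ended under TMM (0.0774), with no low-count filter (0.0823) and in 9 of the 12 leave-outs, all but long-day floret replicate 2 and short-day replicate 1 of both panicle stages, at adjusted p of 0.0516 to 0.207. The count of changed miRNAs was 5, and 2 without 58S long-day floret replicate 1 and 3 without 1.0 to 2.0 cm replicate 2 of either daylength. In the fixed lists, 3 of 5 nutrient and stress miRNAs rose and 1 of 4 phasiRNA triggers fell, adjusted over the list alone and over all miRNAs. In the anther and floral development list 0 of 15 changed over the list alone and 1 rose over all miRNAs.

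Single tags of 58S averaged over stages gave 58 rises and 1926 falls at 21 nt, and 299 rises and 1250 falls among 101210 tags at 24 nt. TGCCAAAGGAGAGTTGCCCTG, a sequence of the miR399 family that governs phosphate uptake, fell from 16.5 ± 5.81 to 3.78 ± 1.23 RPM (n = 6 each; adjusted p = 0.00475, or 0.0559 without 58S long-day 1.0 to 2.0 cm replicate 1). The 24-nt tag ACCATTGTAGAATTTCACCCGAGA fell from 21.6 ± 7.89 to 5.62 ± 4.60 RPM (−3.20 ± 0.31, adjusted p = 9.37e-06). The 21-nt count rests on single libraries. Without long-day libraries it was 4679 and 80 (0.5 to 1.0 cm, replicates 1 and 2), 3 and 137 (1.0 to 2.0 cm), and 42 and 59 (floret). Without short-day libraries it was 3450 and 51, 350 and 109, and 258 and 52, in the same order. The 24-nt count, in that order, was 742 and 507, 464 and 796, and 702 and 466 without long-day libraries. Without short-day libraries it was 418 (0.5 to 1.0 cm replicate 2), 952 and 511, and 722 and 544. TMM turned the 21-nt split to 109 rises and 32 falls and DESeq2 to 587 and 107. With 20 to 24 nt reads as library size it was 47 and 1256, and without the 2 NIL libraries that stood apart it was 243 and 7604, and 1662 and 4236 at 24 nt. Among phased 24-nt contigs, 15 of 39 fell (3 rises and 4 falls under TMM, 8 falls with in-phase tags only, 3 falls among contigs at least 70% in phase), led by PHAS24-038 (5.26 ± 4.17 against 12.4 ± 4.64 RPM, −1.49 ± 0.19, adjusted p = 4.2e-06). PHAS24-028, named after its value was seen, rose by 0.28 (adjusted p = 0.0475). That call was kept in 2 of 12 leave-outs, without 58S long-day 0.5 to 1.0 cm replicate 2 and without long-day floret replicate 2, and the others gave 0.0544 to 0.158. The summed 21-nt tags did not differ by daylength in 58S (mean log2 difference −0.14, exact permutation test within stages, two-sided p = 0.38) nor did the 24-nt tags (0.0062, p = 0.88, or −0.40 with two-sided exact permutation p = 0.0648 for phased contigs in place of tags), in a test over all regroupings within stages whose smallest possible p is 0.009259. The 21-nt mean covers stages that go both ways, −0.52, −0.08 and 0.19 from the youngest panicles to florets, and with phased contigs in place of tags it was −0.40 (two-sided exact permutation p = 0.111). Without any 1 library the 21-nt difference ran from −0.21 to −0.0613.

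The same comparison in NIL(MH) asked whether the daylength change belongs to the sterile line. In NIL(MH) the phased 21-nt small RNAs of panicles of 0.5 to 1.0 cm were alike, at 4811 ± 325 RPM under long and 4871 ± 53.1 under short days (n = 2 each). Over the 3 stages, miR398b rose by 1.72 (adjusted p = 0.000468), miR408-3p by 1.38 (0.00297) and miR528 by 1.11 (0.00297). No phased 21-nt contig changed over the 3 stages by edgeR without a block (43 at an unadjusted p under 0.05, 32 rises and 27 falls by DESeq2, 31 and 22 under TMM), and the median was −0.10. With the replicate number as a block some contigs were called. Without NIL long-day floret replicate 2 the count was 34, and without NIL long-day 1.0 to 2.0 cm replicate 2 it was 27. miR160a, which restrains auxin response factors, rose by 1.87 (adjusted p = 0.00297), but not without NIL long-day 1.0 to 2.0 cm replicate 1 (0.92, 0.104). miR319a, which restrains TCP growth regulators, fell by 0.70 (adjusted p = 0.0183). It did not pass under TMM (0.318) or without long-day floret replicate 1 (0.0558), long-day 0.5 to 1.0 cm replicate 2 (0.0569), long-day 1.0 to 2.0 cm replicate 1 (0.0969), or short-day replicate 2 at 0.5 to 1.0 cm (0.0589) and at 1.0 to 2.0 cm (0.058). miR394 rose by 0.74 (adjusted p = 0.0273). It did not pass by DESeq2 (0.243), under TMM (0.318), without a filter (0.073) or in 8 leave-outs, at 0.0601 to 0.172. The 4 leave-outs in which it passed were long-day replicate 2 of each stage and short-day floret replicate 2. By stage and over all miRNAs, 3 nutrient and stress miRNAs passed in NIL(MH) florets and 0 in its panicles of either size, and 0 of 5 passed the genotype by daylength test. The miRNA count was 6, with 3 without the 2 NIL libraries that stood apart, 12 without long-day floret replicate 2 and 3 without long-day 1.0 to 2.0 cm replicate 1. In the fixed lists, 3 of 5 nutrient and stress miRNAs rose and 2 anther and floral development miRNAs rose and 1 fell, adjusted over the list alone and over all miRNAs.

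In NIL(MH) 3 single 21-nt tags of 31333 changed over the stages (4576 at an unadjusted p under 0.05, 1307 rises and 230 falls by DESeq2, and more than 3 with the replicate number as a block). TGCCAAAGGAGAGTTGCCCTG, the miR399-family tag, fell from 14.6 ± 6.29 to 1.43 ± 0.478 RPM (n = 6 each; −3.30 ± 0.34, adjusted p = 5.69e-05). The others, the second of them named after its value was seen, were ATTGGCTCGGCTAGATACTGC (1.78, adjusted p = 0.0434) and TTACAACCTCGTCTTCTCATG (−2.77, adjusted p = 0.0434). The count was 1846 without NIL long-day floret replicate 2, 2032 without long-day 1.0 to 2.0 cm replicate 2, and 1 without each of the other 10 libraries. By stage, 0 tags changed at 0.5 to 1.0 cm (1473 at an unadjusted p under 0.05; 1 rise and 1 fall by DESeq2). At 1.0 to 2.0 cm 0 changed (3445; 313 rises and 61 falls by DESeq2), or 1804 without long-day replicate 2. In florets the miR399-family tag fell alone, the count being 357 without long-day replicate 2 and 0 without each of the other 3 libraries. It was also 0 under TMM, with TMM factors from 24-nt tags and without the 2 NIL libraries that stood apart, and 17 rises and 1 fall by DESeq2. Among 24-nt tags 299 rose and 349 fell (767 and 458 by DESeq2, 618 and 497 with no low-count filter, 36 and 103 without the 2 NIL libraries that stood apart). Without long-day libraries the 24-nt count was 12 and 1212 (0.5 to 1.0 cm, replicates 1 and 2), 25 and 15636 (1.0 to 2.0 cm), and 38 and 13171 (floret). Without short-day libraries it was 5 and 9, 10 and 6, and 19 and 8. Phased 24-nt contigs fell in 5 cases and rose in 0, with 3 falls by DESeq2, 2 with in-phase tags only and 1 among contigs at least 70% in phase. PHAS24-011 fell from 272.7 ± 93.6 to 169.0 ± 82.6 RPM (adjusted p = 0.000773) and PHAS24-019 also fell (−0.57, adjusted p = 0.0135), though not by DESeq2 (0.117). The other 3, named after their values were seen, were PHAS24-037 (−1.16), PHAS24-038 (−1.11) and PHAS24-015 (−0.45, adjusted p = 0.276 by DESeq2). Summed tags did not pass the test by daylength (21 nt 0.06, two-sided exact permutation p = 0.463; 24 nt 0.09, p = 0.194, over all regroupings within stages, with a smallest possible p of 0.009259). With 20 to 24 nt reads as library size the 24-nt total did pass (0.10, two-sided exact permutation p = 0.037), and with phased contigs in place of tags the 21-nt difference was −0.10.

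The direct test of the difference between the lines was the genotype by daylength interaction. Averaged over stages, miR2275 fell under long days in 58S and did not change past the test in NIL(MH) (1.08, adjusted p = 0.112), and the fall in 58S comes from the panicle stages, not from florets. Its interaction was −2.99 ± 0.63 (adjusted p = 0.00208), or −2.64 (0.122) without NIL long-day 0.5 to 1.0 cm replicate 2, −3.71 without 58S long-day 0.5 to 1.0 cm replicate 2 and −3.82 without NIL short-day 0.5 to 1.0 cm replicate 2. It was the 1 miRNA called, and the count was 5 without NIL long-day floret replicate 2, 4 without NIL long-day 1.0 to 2.0 cm replicate 2, and 3 with no low-count filter. Over the stages 99 phased 21-nt contigs responded more negatively in 58S and 0 more positively (DESeq2 14 and TMM 4 more positively, 1 more negatively in both). That count was 150 without 58S long-day 0.5 to 1.0 cm replicate 1, 22 without 58S short-day replicate 2, 55 and 53 without NIL long-day and short-day replicate 1 of that stage, and 50 without NIL short-day 1.0 to 2.0 cm replicate 2. At 0.5 to 1.0 cm alone it was 178 contigs, with a median interaction of −2.29, and no library moved that count by over 1.5 times, but scaling over the contigs turned it to 11 more positive and 1 more negative (TMM) or 13 and 5 (DESeq2). Single 21-nt tags gave 0 over the stages (6053 at an unadjusted p under 0.05; DESeq2 58 and 64), but 3 more positive and 550 more negative without the 2 NIL libraries that stood apart. The tag count was 1363 without 58S long-day 0.5 to 1.0 cm replicate 1, 2 without 58S short-day replicate 1 of that stage, 476 without NIL long-day floret replicate 2 and 497 without NIL long-day 1.0 to 2.0 cm replicate 2. At 0.5 to 1.0 cm 3 tags were more positive and 4996 more negative, while TMM called 0, DESeq2 593 more positive and 131 more negative, and the fit without the 2 NIL libraries that stood apart 16 and 8782. Without 58S replicate 2 of long and of short days the total was 196 and 1, without NIL long-day replicates 1 and 2 it was 896 and 2921, and without NIL short-day replicates 1 and 2 it was 82 and 1291. Phased 24-nt contigs gave 7, all more negative in 58S, led by PHAS24-024 (−1.18), which was named after its value was seen. The 24-nt count was 13 without 58S long-day 0.5 to 1.0 cm replicate 1, 12 without NIL long-day floret replicate 2 and 11 without NIL long-day 1.0 to 2.0 cm replicate 2. It was 3 without each of 58S long-day floret replicate 2, 58S short-day floret replicate 1, NIL long-day 0.5 to 1.0 cm replicate 2, NIL short-day floret replicate 2 and NIL short-day 1.0 to 2.0 cm replicate 2, and DESeq2 called 1 more negative and TMM 1 more positive. In-phase tags only gave 3, contigs at least 70% in phase 1 and TMM factors from 24-nt tags 11, all more negative.

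Comparing the lines at one daylength asked which small RNAs follow the genotype. Averaged over the 3 stages under long days, 92 phased 21-nt contigs were lower in 58S than in NIL(MH) and 2 were higher. Of the 86 called with a mean of at least 5 RPM, 3 had lines that did not overlap within each stage. Of 100 regroupings of the libraries, the real one included, 16 gave as many calls. PHAS21-155 stood at 3.61 ± 2.28 in 58S against 15.1 ± 6.69 RPM in NIL(MH) (n = 6 each, −2.30 ± 0.22, adjusted p = 5.41e-09). Scaling over the contigs turned the split to 15 higher and 6 lower by TMM and to 19 and 8 by DESeq2. The total of 94 became 146 without 58S long-day 0.5 to 1.0 cm replicate 1, 47 without its replicate 2, 60 without 58S long-day 1.0 to 2.0 cm replicate 1, 61 without 58S long-day floret replicate 2 and 50 without NIL long-day 0.5 to 1.0 cm replicate 1. Under short days the median contig stood at 0.18. The 3 contigs called under short days, chosen after their values were seen, were PHAS21-154 (1.77 ± 0.29, adjusted p = 0.000106), PHAS21-181 (1.70, 0.0053) and PHAS21-155 (−1.42, 1.79e-05). PHAS21-181 did not pass without 58S short-day 0.5 to 1.0 cm replicate 2 (0.0847) or NIL short-day 0.5 to 1.0 cm replicate 1 (0.0672), and stood at 2.82 without NIL short-day 0.5 to 1.0 cm replicate 2. Without 58S short-day 0.5 to 1.0 cm replicate 1 the count was 6, and TMM and DESeq2 each called 3 higher and 3 lower. The rises under long days were PHAS21-154 and PHAS21-002 (0.48, adjusted p = 0.0186). PHAS21-002, named after its value was seen, did not pass without NIL long-day 1.0 to 2.0 cm replicate 1 (0.0503).

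Of the 21-nt tags, 459 were higher and 1468 lower in 58S under long days, and some had no read in the long-day libraries of 1 line. TCACTCCAGATCTTGTCCAAC had 22.3 ± 18.3 RPM in long-day 58S and no read in long-day NIL(MH), at least 572-fold higher, and TTTTTCCTGATCGATGGCATG had none in long-day 58S and 47.5 ± 31.1 RPM in long-day NIL(MH), at least 964-fold lower (floor of 3 counts over the group). Under short days, a count added after the data were examined, 553 tags were higher and 281 lower in 58S. Under TMM the long-day split was 595 higher and 621 lower, and by DESeq2 784 and 942. The total of 1927 became 991 without 58S long-day 0.5 to 1.0 cm replicate 2, 1035 and 1235 without replicates 1 and 2 of 58S long-day 1.0 to 2.0 cm, 1150 and 1012 without those of 58S long-day floret, 961 without NIL long-day 0.5 to 1.0 cm replicate 1, 1018 and 3206 without those of NIL long-day 1.0 to 2.0 cm, and 1127 and 3193 without those of NIL long-day floret. Of the miRNAs, miR2275 (−1.78, adjusted p = 0.0143) and miR160a (−2.08, adjusted p = 0.00391) were lower in 58S. Without NIL long-day 1.0 to 2.0 cm replicate 1 neither passed (0.0656 and 0.0773). miR2275 did not pass without 58S long-day 0.5 to 1.0 cm replicate 1 (0.0765) or NIL long-day 0.5 to 1.0 cm replicate 2 (0.144), and stood at −2.50 without 58S long-day 0.5 to 1.0 cm replicate 2. The count of 2 became 0 without NIL long-day 1.0 to 2.0 cm replicate 1, 10 without its replicate 2, 11 without NIL long-day floret replicate 2, 1 without NIL long-day 0.5 to 1.0 cm replicate 2, 4 without 58S long-day 1.0 to 2.0 cm replicate 2, 4 with no low-count filter and 0 without the 2 NIL libraries that stood apart. Adjusted over the fixed list alone, 1 phase change miRNA was higher and 1 nutrient and stress miRNA lower (both 0 over all). Of anther and floral development miRNAs 1 was higher and 1 lower (0 and 1 over all).

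Stage comparisons, averaged over lines and daylengths, asked when the small RNAs of anther development accumulate. From panicles of 0.5 to 1.0 cm to those of 1.0 to 2.0 cm the 21-nt phasiRNA class built up: 189 of 191 phased contigs rose and 0 fell, and miR2118 rose from 493.3 to 1078 RPM (n = 8 each; 1.24, adjusted p = 5.18e-06). PHAS21-015 rose from 15.6 ± 12.7 to 96.5 ± 26.1 RPM (adjusted p = 4.1e-12). Scaling over the contigs gave 41 rises and 33 falls by TMM and 41 and 36 by DESeq2. miR2275 rose by 3.76 (adjusted p = 3.39e-08), or 4.39 without NIL short-day 0.5 to 1.0 cm replicate 2, miR528 by 1.24 and the growth regulators miR396e by 1.03 and miR396c by 0.94. miR156 fell by 0.99, miR319a by 0.83 and the auxin pathway miR167a by 0.76. The count of 9 miRNAs was 14 without 58S short-day 0.5 to 1.0 cm replicate 2 and 17 without the 2 NIL libraries that stood apart. Single 21-nt tags gave 22346 rises and 288 falls, turning to 3985 and 4272 under TMM and to 3833 and 4493 by DESeq2. Single 24-nt tags gave 3224 rises and 186 falls, the total becoming 2150 without 58S long-day 0.5 to 1.0 cm replicate 2, 2252 without 58S long-day 1.0 to 2.0 cm replicate 2, 6752 without NIL long-day 1.0 to 2.0 cm replicate 2, 2273 without NIL short-day 1.0 to 2.0 cm replicate 1 and 6041 without the 2 NIL libraries that stood apart. Of the phased 24-nt contigs 16 rose (5 of those at least 70% in phase) and 1 fell, PHAS24-028 (−0.43), named after its value was seen. Adjusted over the list alone, 2 phasiRNA triggers rose and 1 fell (2 and 0 over all), 4 nutrient and stress miRNAs rose (1 over all), 3 anther and floral development miRNAs rose and 2 fell on both counts, and 1 phase change miRNA fell on both.

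From panicles of 1.0 to 2.0 cm to florets of 3.0 to 4.0 mm, phased 24-nt contigs changed in both directions, and the largest changes were rises. PHAS24-029 rose from 0.153 ± 0.312 to 190.6 ± 43.5 RPM (n = 8 each; adjusted p = 2.96e-15) and PHAS24-031 from 0.142 ± 0.241 to 163.6 ± 67.8, and miR2275 rose from 2.20 to 125.2 RPM (6.02, adjusted p = 5.69e-16). Of 39 phased 24-nt contigs 23 rose and 15 fell (16 and 1 of those at least 70% in phase), with PHAS24-037 (−1.93) among the falls. Without 58S long-day 1.0 to 2.0 cm replicate 2 the change of PHAS24-029 was 13.10, and that of PHAS24-031 was 11.78 without 58S short-day 1.0 to 2.0 cm replicate 1 and 11.84 without NIL short-day 1.0 to 2.0 cm replicate 1. miR827, of phosphate homeostasis, rose from 0.264 to 21.3 RPM, and by 7.41 on the log2 scale without 58S short-day 1.0 to 2.0 cm replicate 2. miR167d rose by 3.98, miR164a, which bounds floral organs, by 3.13, and miR396e by 3.47. miR159f, which restrains anther GAMYB factors, fell by 2.35 (adjusted p = 1.52e-05), or −3.58 without NIL long-day floret replicate 2, and miR319a by 1.55. In all 14 miRNAs rose and 7 fell. miR2118 did not change (0.14, adjusted p = 0.438), standing at −0.35 by DESeq2 and −0.05 under TMM. Phased 21-nt contigs rose in 124 cases and fell in 7 (TMM 54 and 53, DESeq2 56 and 51). Single 21-nt tags gave 10492 rises and 2308 falls (TMM 3760 and 4802, DESeq2 5276 and 4086), and 24-nt tags 11020 rises and 23350 falls (TMM 12665 and 6452, DESeq2 11038 and 4527). TTAGGTTGCCGGTGTAGAAGC, with 22.6 ± 6.91 RPM in florets, had no read in the panicles of 1.0 to 2.0 cm, at least 714-fold lower. In the fixed lists, adjusted over the list alone, 1 phasiRNA trigger rose and 2 fell, 7 anther and floral development miRNAs rose and 3 fell, 5 nutrient and stress miRNAs rose and 1 small RNA machinery miRNA rose, each the same over all miRNAs. In the phase change list 1 rose and 2 fell over the list alone, and 0 and 2 over all.

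**Figure D3:**
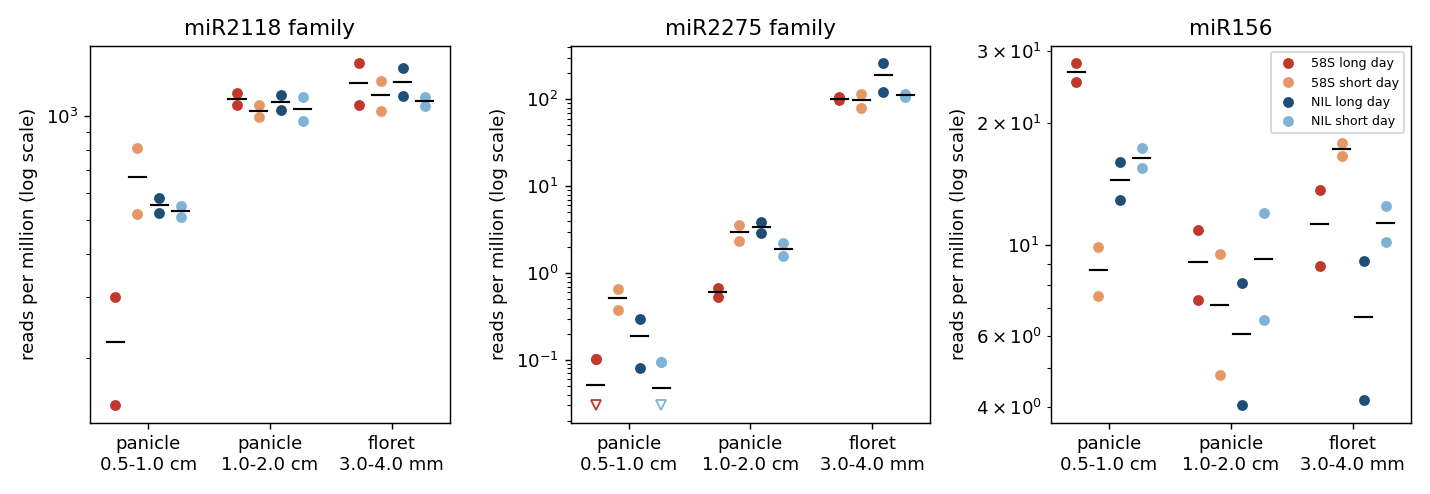
Abundance (RPM, log axis) of miR2118, miR2275 and miR156 by line, stage and daylength; points are libraries, bars are means and open triangles are libraries with 0 reads. miR2275 climbs from 0.202 RPM in the youngest panicles to 125.2 in florets.

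The transgenic plants asked what PMS1T level does to small RNAs. A single phased contig, PHAS21-154 (382 nt), answered to both constructs: it rose in the overexpressors from 8.47 ± 1.57 to 39.2 ± 6.97 RPM (n = 2 each; 2.22 ± 0.16, adjusted p = 8.31e-14) and in the RNAi plants from 12.1 ± 1.95 to 284.8 ± 2.83 RPM (4.56, adjusted p = 3.99e-24). It is the candidate for the PMS1T transcript, chosen by a ranking of 5527 contigs in the RNAi plants in which it was the 1 raised contig above 0.5 RPM in the lines. The RNAi rise was siRNA out of phase: 2.79% of its reads were in phase in RNAi-positive plants (95% Clopper-Pearson interval 2.47 to 3.14), against 97.2% in RNAi-negative plants (95.2 to 98.5). Its in-phase reads were 7.99 ± 1.29 against 11.8 ± 1.94 RPM, a difference not past the test (−0.56 ± 0.18, adjusted p = 0.111). In overexpressors 75.7% were in phase (73.7 to 77.7) and in their negatives 98.3% (96.1 to 99.5), and the in-phase reads alone rose by 1.84 ± 0.17. At position 360, counted from the first base of the contig, A360C separates the lines, with 54 reads of the first base and 0 of the second in 58S and 0 and 104 in NIL(MH). Overexpressors had 134 and 4 and their negatives 0 and 28, while RNAi-positive and RNAi-negative plants had 14 and 12 reads of the 58S base and 0 of the other.

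**Figure D4:**
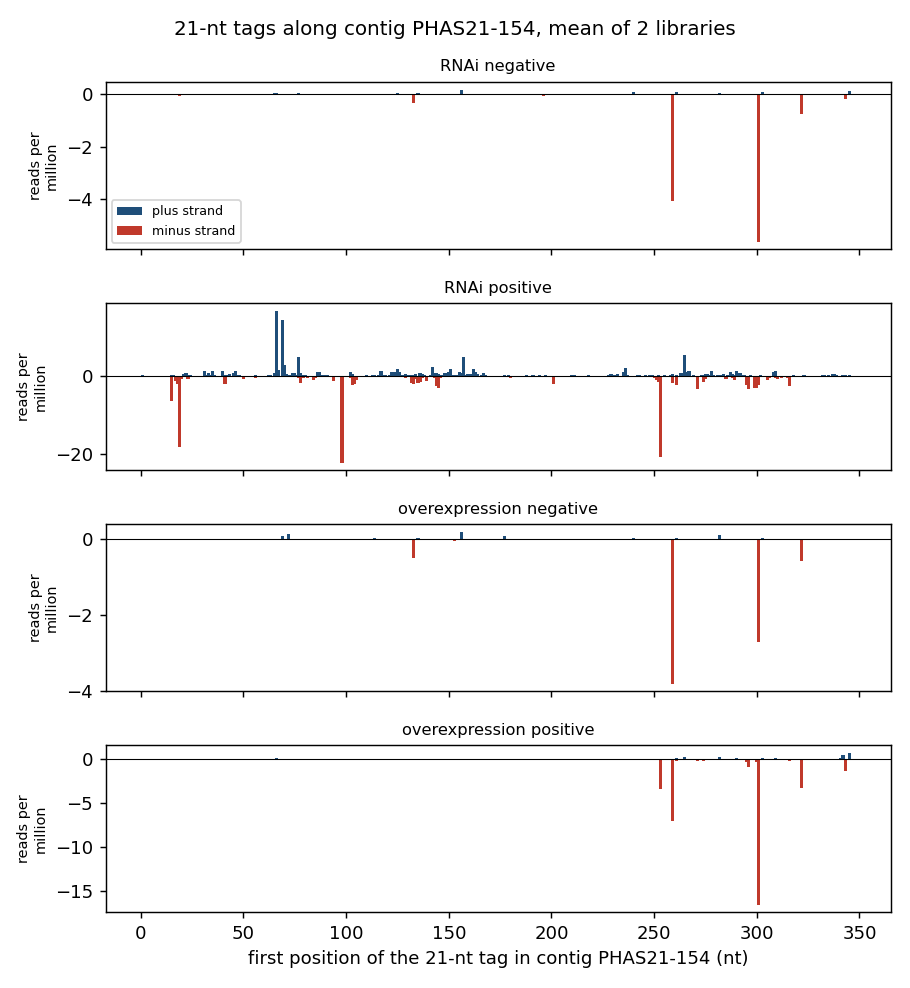
Reads (RPM, mean of 2 libraries) by position along PHAS21-154 in transgene-positive and transgene-negative plants. RNAi-positive plants reach 284.8 RPM over the contig, spread over positions out of the 21-nt register.

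In the lines, PHAS21-154 followed the young panicle pattern. In 58S panicles of 0.5 to 1.0 cm it had 1.60 ± 1.97 RPM under long and 13.1 ± 4.91 under short days (−2.91 ± 0.52, adjusted p = 1.3e-05), or −5.93 and −2.15 without long-day replicates 1 and 2. It did not pass there by DESeq2 (−0.64, 0.306) or TMM (−0.72, 0.254). At 1.0 to 2.0 cm it had 29.7 ± 1.09 against 24.6 ± 1.05 RPM, and in florets 14.7 ± 0.506 against 10.4 ± 0.229. Over the stages it fell by 0.72 (adjusted p = 0.0175), which became −1.72 without 58S long-day 0.5 to 1.0 cm replicate 1, did not pass without short-day replicate 2 of that stage (0.0847), and turned to 0.08 by DESeq2 and 0.07 under TMM. It did not change in NIL(MH) (0.21, adjusted p = 0.716), and the interaction was −0.92 (adjusted p = 0.0533). It passed without 58S long-day and short-day 0.5 to 1.0 cm replicate 1 (0.000382 and 0.0324) and without NIL long-day replicate 1 of floret (0.028) and 1.0 to 2.0 cm (0.026). Under long days, averaged over stages, it was higher in 58S than in NIL(MH) by 0.85 (adjusted p = 0.0201), but stood at −0.16 without 58S long-day 0.5 to 1.0 cm replicate 1 and did not pass with reads of both alleles counted (0.60, adjusted p = 0.0796). By stage that difference was −0.94, 1.58 and 1.89 from the youngest panicles to florets, and no stage passed the test. It rose with panicle size by 2.21 (2.96 without 58S long-day 0.5 to 1.0 cm replicate 1) and fell in florets by 1.35.

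In overexpressors 14 of 191 phased 21-nt contigs rose and 11 fell (27 and 23 under TMM, 21 and 19 by DESeq2), and PHAS21-110 fell from 44.6 ± 1.33 to 26.6 ± 0.786 RPM (adjusted p = 0.000137). The total of 25 became 13 and 15 without OX-negative replicates 1 and 2 and 14 and 4 without OX-positive replicates 1 and 2. In RNAi plants 1 rose and 2 fell (35 at an unadjusted p under 0.05; 5 rises and 2 falls by DESeq2, 5 and 1 under TMM; 0 and 1 with in-phase tags only): PHAS21-126 (14.4 ± 2.38 against 22.4 ± 0.395 RPM, adjusted p = 0.00782) and PHAS21-060 (−0.55, adjusted p = 0.0484). PHAS21-126 did not pass without RNAi-positive replicate 2 (0.166), nor did PHAS21-060 (0.375, and 0.36 without RNAi-negative replicate 2). The count of 3 became 5 without RNAi-negative replicate 1, and 20 and 1 without RNAi-positive replicates 1 and 2. Of 36098 tags, 475 rose and 517 fell in overexpressors (786 and 884 under TMM), the total being 87 and 45 without OX-negative replicates 1 and 2 and 1883 and 472 without OX-positive replicates 1 and 2. GAAGATTAGAACTTACTCGGT rose from 2.70 ± 0.284 to 16.5 ± 2.86 RPM (adjusted p = 2.91e-07). In RNAi plants 492 tags rose, 480 of them under the minimum count in the lines, and 140 fell. TGTAGGCAAGGGAAGTCGGCA, which met the line minimum, rose from 9.34 ± 0.206 to 21.9 ± 2.25 RPM (adjusted p = 0.000106). Pieces of ribosomal RNA were not set apart, so whether this tag is one was not checked. Of the miRNAs, miR393a, which restrains auxin receptors, fell in overexpressors by 0.76 (adjusted p = 0.0498). It did not pass without OX-negative replicates 1 (0.126) and 2 (0.187), without OX-positive replicate 2 (0.07) or with 20 to 24 nt reads as library size (0.0524), and without OX-positive replicate 1 the miRNA count was 4. Under TMM 4 miRNAs rose and 2 fell, by DESeq2 4 rose and 3 fell, and with the abundant miR529 variant 1 rose and 1 fell. In RNAi plants 0 miRNAs changed by edgeR (4 at an unadjusted p under 0.05; 0 by DESeq2, but 1 rise and 1 fall under TMM). In the fixed lists, adjusted over the list alone, overexpressors had 2 anther and floral development miRNAs up and 4 down (0 and 1 over all) and the 1 monocot MADS-box regulator down (0 over all), and RNAi plants had 1 small RNA machinery miRNA up (0 over all).

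PARE asked where miR2118 and miR2275 cut the precursors of phasiRNAs. Predicted miR2118 sites lay in 5 of the 191 phased 21-nt contigs, PHAS21-011, PHAS21-012, PHAS21-071, PHAS21-094 and PHAS21-152. All 5 had PARE ends there, and the first 4 were cut in register. PARE tags were among those assembled, so PARE ends in these contigs are in part built in. These sites held 376.1 RPM in NIL(MH) short days (95% exact interval 370 to 383), 289.8 in NIL(MH) long days (284 to 296), 259.0 in 58S long days (254 to 264) and 192.1 in 58S short days (188 to 197). With 1 library per group no difference was tested. In each of 20 sets shuffled miRNA sequences gave sites in at most 1 contig. This controls the site search, not the PARE ends. The 2 predicted miR2275 sites had 0 reads in each library (upper limit 0.087 to 0.108 RPM). miR2275 had 11 to 134 small RNA reads per group at the PARE stage and 1611 to 3292 in florets, so whether it cuts stays open.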

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

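The tests of read composition, of reads from the other line, of phasiRNA production in the RNAi plants, of other splits of the NIL libraries for phased 21-nt contigs, of other splits of the lines under short days and of other splits for genotype by daylength in phased 24-nt contigs were chosen only after the results were seen.

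Interaction tests with library size as the only scaling called daylength responses that differ between the lines and between stages. Over the stages 99 phased 21-nt contigs responded to daylength differently in 58S and NIL(MH). In panicles of 0.5 to 1.0 cm 178 contigs and 4999 single 21-nt tags did so, as did 7 phased 24-nt contigs over the stages. Within 58S the response at 0.5 to 1.0 cm differed from that at 1.0 to 2.0 cm in 177 phased 21-nt contigs and from that in florets in 183. These calls rest on the scaling. Under TMM the contigs were 4 higher and 1 lower in 58S over the stages and 11 and 1 at 0.5 to 1.0 cm, the tags 0, the phased 24-nt contigs 1 higher and the stage contrasts 2 and 4 higher and 0 lower. DESeq2 gave 14 and 1, 13 and 5, 593 and 131 tags, 1 phased 24-nt contig lower, and 4 and 5 higher. The miR2275 response was lower in 58S than in NIL(MH) by interaction (−2.99). Within 58S the response at 0.5 to 1.0 cm minus that in florets was −1.70 for miR2118, −3.57 for miR2275 and 2.23 for miR156, each at an adjusted p of 0.0288. Leaving out 1 of the 8 libraries ended the miR2118 call (0.0655 to 0.31) except without 58S 0.5 to 1.0 cm replicate 1 of long days (0.00448) or of short days. It ended the miR2275 call (0.0655 to 0.631) except without long-day replicate 2 of that stage (0.0482) or short-day replicate 1, and the miR156 call every time (0.0571 to 0.31).

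A signal also appeared outside the lengths compared. A single 34-nt tag held a median of 432.3 reads per 1000000 reads of all lengths over the small RNA libraries. It had 7218 to 9314 in the floret groups, 332 to 875 in the panicle groups of the lines and 90.1 to 183 in the transgenic groups. It lies outside the 18 to 30 nt reads used as library size, and no explanation of it was tested.

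The loss of phased 21-nt small RNAs in 58S panicles of 0.5 to 1.0 cm under long days is the first pattern weighed. A different read composition was weighed by the 24-nt tags, whose median change was 0.02 against −2.14 for 21-nt tags. Reads of 24 nt made up 54.7% of the library size under long days and 50.2% under short days at this stage. Their median can thus stay near 0 even if 21-nt reads are lost, so the test cannot decide on composition. The summed phased 24-nt contigs changed by −1.01 on the log2 scale at this stage, against −1.14 for the phased 21-nt contigs. The long-day panicles may have been younger within the size class. Across the 26 miRNAs compared, which are features and not independent replicates, r between the daylength and size changes was −0.586. The planned test of this on 24-nt tags rests on 1 tag, whose change was −3.318, so younger panicles and a daylength effect cannot be told apart, and a biological effect of daylength in 58S stays open and untested. Nor can daylength be told apart from whatever else differed between the field conditions.

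The second pattern is that NIL long-day 1.0 to 2.0 cm replicate 1 and NIL long-day floret replicate 1 stood apart from their replicates, with an SD of the log2 difference of 1.57 and 1.62 against 0.53 to 0.94 in the other groups. Their deviations went with the contrast between the transgenic libraries and the libraries of the lines at r = 0.788 and 0.76 across tags, which are not independent replicates, where the other 10 groups had −0.062 to 0.269. That is consistent with a library batch shared with the transgenic libraries, although the labels give no batch. Reads from the other line cannot be judged here, although 0 of 20 reads at the allele position were of the 58S base. The position was chosen for separating the lines in pooled libraries that included these 2, so that result was largely fixed in advance. No biological explanation was tested.

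The third pattern is the siRNA of PHAS21-154 in RNAi-positive plants, which rose while leaving the 21-nt register. More phasiRNA production would raise in-phase reads, but these changed by −0.556 with an SE of 0.183 (edgeR, adjusted p = 0.111). The rise was thus not one of in-phase reads. The share in phase was already known when this test was chosen, so it is no separate test of phasiRNA production. That the hairpin itself may be the source of the out-of-phase siRNA stays open and was not tested.

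Other splits of the same libraries into groups of equal size were fitted for each count, the real split included. The splits ignore the replicate numbers, which may underlie the sample structure named below. By the rule used, a count matched by fewer than 5 in 100 splits is called unlikely by chance. No allowance was made for the many counts compared, so chance is not excluded for any of them. For 58S by daylength, 4 of 100 splits gave as many 21-nt tags (1984 real, 3311 the highest other) and 2 of 100 as many miRNAs (5 and 5). As many 24-nt tags came from 1 of 40 (1549 and 352), so these counts are unlikely by chance. The 3311 tags of another split leave room for a structure of the samples beside daylength. Phased 21-nt contigs did not meet the rule, with 22 of 100 splits (166 and 179), nor did phased 24-nt contigs, with 5 of 40 (16 and 22). For NIL by daylength chance is unlikely for miRNAs (1 of 100, 6 and 5) and phased 24-nt contigs (1 of 40, 5 and 3). The rule was not met by 21-nt tags (6 of 100, 3 and 658) or 24-nt tags (3 of 40, 648 and 2034). The 658 and 2034 tags point to a structure of the samples other than daylength. For phased 21-nt contigs the real count was 0 (1 the highest other), so every split gives as many and the count of splits tells nothing. For 58S against NIL under long days 21-nt tags met the rule (3 of 100, 1927 and 2912, which again leaves room for such a structure). Phased 21-nt contigs (16 of 100, 94 and 163) and miRNAs (18 of 100, 2 and 5) did not. Under short days, a split count added later, the rule was met by 21-nt tags (1 of 100, 834 and 555) and phased 21-nt contigs (1 of 100, 3 and 1). For genotype by daylength the rule was not met by phased 21-nt contigs (6 of 100, 99 and 138), phased 24-nt contigs (4 of 40, 7 and 12) or miRNAs (6 of 100, 1 and 3). For 21-nt tags the real count was 0, so every split gives as many and the count tells nothing of chance, but the 474 tags of another split point to a structure of the samples.

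For the stages chance is unlikely by the same rule throughout, although another split matched the counts of phased 21-nt contigs and of miRNAs between panicle sizes. Large against small panicles gave 1 of 100 for 21-nt tags (22634 real, 20534 the highest other), 2 of 100 for phased 21-nt contigs (189 and 189) and for miRNAs (9 and 9), and 1 of 40 for 24-nt tags (3410 and 0) and phased 24-nt contigs (17 and 14). Florets against large panicles gave 1 of 100 for 21-nt tags (12800 and 4472), phased 21-nt contigs (131 and 89) and miRNAs (21 and 13), and 1 of 40 for 24-nt tags (34370 and 4663) and phased 24-nt contigs (38 and 32).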

How the results depend on the processing

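The tests with phased contigs, with the 2 NIL libraries that stood apart left out, with TMM factors from 24-nt tags, with in-phase tags only, with contigs at least 70% in phase, with tags shared between contigs, with both alleles, with the abundant miR529 variant, and those of added contrasts were chosen only after the results were seen. Of 978 recomputed counts and totals, 749 kept their direction and side of the test or lay within 1.5 times the reported count, 222 moved further, 1 gained the threshold and 6 changed sign. Of 4782 recomputed values of named miRNAs, tags, contigs and cleavage sites, 4363 kept direction and call, 397 lost the call, 11 gained it, 3 moved with no test and 8 changed sign. Losses of the call came to 288 with 1 library left out, 34 under TMM, 31 under DESeq2, 15 without the NIL libraries that stood apart and 8 with in-phase tags only. Small and large panicles below are those of 0.5 to 1.0 cm and of 1.0 to 2.0 cm, and numbers are features past the adjusted p of 0.05.

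TMM scaling over the tested features gave, among 21-nt tags, 141 for 58S by daylength (109 up, 32 down), 1216 for 58S against NIL under long days (595 up, 621 down), 8257 for large against small panicles (3985 up, 4272 down), 1670 for overexpressors (786 up, 884 down), 1008 for 58S small panicles (824 up, 184 down), 0 for NIL florets and 0 for genotype by daylength in small panicles. Among 24-nt tags it gave 19117 for florets against large panicles (12665 up, 6452 down). Among miRNAs it gave 6 for overexpressors (4 up, 2 down) and 2 for RNAi plants (1 up, 1 down). Among phased 21-nt contigs it gave 12 for 58S by daylength (8 up, 4 down), 53 for NIL by daylength (31 up, 22 down), 5 for genotype by daylength (4 up, 1 down), 21 for 58S against NIL under long days (15 up, 6 down), 6 for 58S against NIL under short days (3 up, 3 down), 74 for large against small panicles (41 up, 33 down), 50 for overexpressors (27 up, 23 down), 6 for RNAi plants (5 up, 1 down), 10 for 58S small panicles (7 up, 3 down), 2 for the 58S daylength change in small minus large panicles (2 up, 0 down), 4 for the 58S daylength change in small panicles minus florets (4 up, 0 down) and 12 for genotype by daylength in small panicles (11 up, 1 down). Among phased 24-nt contigs it gave 7 for 58S by daylength (3 up, 4 down) and 1 for genotype by daylength (1 up, 0 down).

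DESeq2 gave, among 21-nt tags, 694 for 58S by daylength (587 up, 107 down), 1537 for NIL by daylength (1307 up, 230 down), 122 for genotype by daylength (58 up, 64 down), 8326 for large against small panicles (3833 up, 4493 down), 2537 for 58S small panicles (2371 up, 166 down), 2 for 58S large panicles (0 up, 2 down), 15 for 58S florets (12 up, 3 down), 2 for NIL small panicles (1 up, 1 down), 374 for NIL large panicles (313 up, 61 down), 18 for NIL florets (17 up, 1 down) and 724 for genotype by daylength in small panicles (593 up, 131 down). Among 24-nt tags it gave 1225 for NIL by daylength (767 up, 458 down) and 15565 for florets against large panicles (11038 up, 4527 down). Among miRNAs it gave 7 for overexpressors (4 up, 3 down). Among phased 21-nt contigs it gave 14 for 58S by daylength (8 up, 6 down), 59 for NIL by daylength (32 up, 27 down), 15 for genotype by daylength (14 up, 1 down), 27 for 58S against NIL under long days (19 up, 8 down), 6 for 58S against NIL under short days (3 up, 3 down), 77 for large against small panicles (41 up, 36 down), 40 for overexpressors (21 up, 19 down), 7 for RNAi plants (5 up, 2 down), 13 for 58S small panicles (9 up, 4 down), 4 for the 58S daylength change in small minus large panicles (4 up, 0 down), 5 for the 58S daylength change in small panicles minus florets (5 up, 0 down) and 18 for genotype by daylength in small panicles (13 up, 5 down). Among phased 24-nt contigs it gave 3 for NIL by daylength (0 up, 3 down) and 1 for genotype by daylength (0 up, 1 down). TMM scaling and DESeq2 centre the features they are computed on, so a change common to a whole class is taken out by construction, which is how falls of 21-nt tags and contigs in 58S turn into mixed splits. The median 21-nt tag change between 58S small panicles of the 2 daylengths is −2.14 before such scaling. Under DESeq2 the miR2118 change over the stages in NIL stood at −0.277 and that from large panicles to florets at −0.346 (TMM −0.052), and PHAS21-154 in 58S by daylength stood at 0.079 (TMM 0.069).

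TMM factors from 24-nt tags gave, among 21-nt tags, 0 for NIL florets. Among phased 24-nt contigs it gave 11 for genotype by daylength (0 up, 11 down). Library size from 20 to 24 nt reads gave, among 21-nt tags, 1303 for 58S by daylength (47 up, 1256 down). Among miRNAs it gave 0 for overexpressors. With that library size the 24-nt total of NIL by daylength passed the exact permutation test (0.1022, two-sided p = 0.037). No low-count filter gave, among 24-nt tags, 1115 for NIL by daylength (618 up, 497 down). Among miRNAs it gave 3 for genotype by daylength (0 up, 3 down) and 4 for 58S against NIL under long days (0 up, 4 down). The cause was not tested for these shifts.

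The replicate number as a block (replicate block) gave, among 21-nt tags, 3177 for 58S by daylength (101 up, 3076 down), 90 for NIL by daylength (68 up, 22 down), 1 for 58S large panicles (0 up, 1 down) and 6 for 58S florets (5 up, 1 down). Among 24-nt tags it gave 2494 for NIL by daylength (1226 up, 1268 down). Among miRNAs it gave 5 for 58S against NIL under long days (2 up, 3 down) and 14 for large against small panicles (8 up, 6 down). Among phased 21-nt contigs it gave 7 for NIL by daylength (1 up, 6 down). Pairing was checked by correlating replicate deviations between groups. Of 66 pairs of groups 60 exceeded 0.1, with a range of −0.016 to 0.912 in 21-nt tags and 0.008 to 0.849 in 24-nt tags. Within the 58S groups the lowest were 0.136 and 0.095, and the transgenic groups ran from −0.046 to 0.314. Replicate 2 held the larger share of reads outside 20 to 24 nt in 12 of 12 line groups. Both checks point to a difference shared by number in the lines, which the main fits and splits leave in. Not every pair exceeded 0.1 and no label states a batch, so the libraries were not paired. That was chosen after some block counts were seen. The block removes such a difference, whose cause was not tested.

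Leaving out NIL long-day large panicle replicate 1 and NIL long-day floret replicate 1 gave, among 21-nt tags, 7847 for 58S by daylength (243 up, 7604 down), 1 for NIL by daylength (0 up, 1 down), 553 for genotype by daylength (3 up, 550 down), 1 for 58S large panicles (0 up, 1 down), 9 for 58S florets (8 up, 1 down), 0 for NIL florets and 8798 for genotype by daylength in small panicles (16 up, 8782 down). Among 24-nt tags it gave 5898 for 58S by daylength (1662 up, 4236 down), 139 for NIL by daylength (36 up, 103 down) and 6041 for large against small panicles (5055 up, 986 down). Among miRNAs it gave 3 for NIL by daylength (3 up, 0 down), 0 for 58S against NIL under long days and 17 for large against small panicles (9 up, 8 down). Fewer samples with a smaller spread are tested in that setting.

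Counting in-phase tags only gave, among phased 21-nt contigs, 1 for RNAi plants (0 up, 1 down). Among phased 24-nt contigs it gave 8 for 58S by daylength (0 up, 8 down), 2 for NIL by daylength (0 up, 2 down) and 3 for genotype by daylength (0 up, 3 down). Keeping contigs at least 70% in phase gave, among phased 24-nt contigs, 3 for 58S by daylength (0 up, 3 down), 1 for NIL by daylength (0 up, 1 down), 1 for genotype by daylength (0 up, 1 down), 5 for large against small panicles (5 up, 0 down) and 17 for florets against large panicles (16 up, 1 down). Adding the abundant miR529 variant gave, among miRNAs, 2 for overexpressors (1 up, 1 down). Fewer reads or contigs are tested in the first pair of settings. In-phase tags turned PHAS21-154 in RNAi plants to −0.556 and PHAS21-137 in overexpressors to −0.38. Phased contigs in place of tags moved the 21-nt total of 58S by daylength to −0.4036 and turned that of NIL to −0.0985 and the 24-nt total of 58S to −0.3984, and the cause was not tested. A target penalty of at most 4 left 4 contigs with sites and lowered the miR2118 cleavage values of all 4 libraries, in 3 of them below the 95% exact interval of the reported value. Shared tags, both alleles and the exact cleavage position moved no count or total, but with both alleles counted PHAS21-154 was no longer past the threshold in 58S against NIL under long days (0.604, adjusted p = 0.0796).

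Leaving out 1 library at a time, the lone library of a group being assumed to vary like the others, the 21-nt tags ran 3 to 4679 for 58S by daylength, 1 to 2032 for NIL by daylength, 0 to 1363 for genotype by daylength, 961 to 3206 for 58S against NIL under long days, 22076 to 23985 for large against small panicles, 11015 to 15541 for florets against large panicles, 45 to 1883 for overexpressors, 427 to 733 for RNAi plants, 1771 to 13063 for 58S small panicles, 0 throughout for 58S large panicles, 0 throughout for 58S florets, 0 throughout for NIL small panicles, 0 to 1804 for NIL large panicles, 0 to 357 for NIL florets, 1 to 6668 for genotype by daylength in small panicles and 706 to 898 for 58S against NIL under short days. The 24-nt tags ran 418 to 1048 for 58S by daylength, 5 to 15636 for NIL by daylength, 2150 to 6752 for large against small panicles and 31884 to 42017 for florets against large panicles. The miRNAs ran 2 to 5 for 58S by daylength, 3 to 12 for NIL by daylength, 0 to 5 for genotype by daylength, 0 to 11 for 58S against NIL under long days, 8 to 14 for large against small panicles, 18 to 23 for florets against large panicles, 0 to 4 for overexpressors and 0 throughout for RNAi plants. The phased 21-nt contigs ran 133 to 181 for 58S by daylength, 0 to 34 for NIL by daylength, 22 to 150 for genotype by daylength, 47 to 146 for 58S against NIL under long days, 2 to 6 for 58S against NIL under short days, 189 throughout for large against small panicles, 116 to 136 for florets against large panicles, 4 to 15 for overexpressors, 1 to 20 for RNAi plants, 169 to 187 for 58S small panicles, 0 throughout for 58S large panicles, 0 throughout for 58S florets, 135 to 180 for the 58S daylength change in small minus large panicles, 159 to 183 for the 58S daylength change in small panicles minus florets and 143 to 181 for genotype by daylength in small panicles. The phased 24-nt contigs ran 13 to 15 for 58S by daylength, 5 to 6 for NIL by daylength, 3 to 13 for genotype by daylength, 16 to 18 for large against small panicles and 38 throughout for florets against large panicles. The log2 totals ran −0.2093 to −0.0613 for the 21-nt total of 58S by daylength, 0.0325 to 0.0928 for the 21-nt total of NIL by daylength, −0.0201 to 0.0325 for the 24-nt total of 58S by daylength and 0.0477 to 0.1226 for the 24-nt total of NIL by daylength. The 24-nt total of 58S changed sign without long-day large panicle replicate 1 (−0.0098), long-day floret replicate 1 (−0.0201), short-day large panicle replicate 1 (−0.0071) and short-day floret replicate 2 (−0.0115), and PHAS21-154 in 58S against NIL under long days changed sign without 58S long-day 0.5 to 1.0 cm replicate 1 (−0.159) and reached 1.104 without its replicate 2.

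On simulated data with 6 libraries per daylength, 2-fold changes of 21-nt tags were recovered in 6% of cases and 4-fold changes in 60%, and with 2 libraries against 2 at 1 stage in 0% and 0%. The alternatives of a stricter phase score and of tags with several genome matches, named before the data were examined, were not run, because no genome was used.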

Other observations

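The seed-only site search, the allele counts and the RNAi ranking were tests chosen only after the results were seen.

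The ranking of contigs in the RNAi plants left 6 of 5527 contigs raised, of which 1 reached 0.5 RPM in the lines and 5 did not, and 11 fell. PARE reads on the plus strand of PHAS21-154 numbered 11, 27, 21 and 33 in the NIL long-day, 58S long-day, NIL short-day and 58S short-day libraries. Seed-only sites of miR2118, in which the first 10 nt pair, gathered 2896 RPM of PARE reads in NIL long days, 2528 in 58S long days, 3690 in NIL short days and 1843 in 58S short days. Shuffled sequences reached at most 82.8, 69.0, 98.7 and 64.9 RPM in the same order. The summed phased 24-nt contigs rose from 1077 ± 135 RPM in 58S long-day panicles of 0.5 to 1.0 cm to 20361 ± 1871 in 58S long-day florets (n = 2 each). In NIL(MH) florets they came to 26438 ± 792 RPM under long days and 20482 ± 862 under short days, a pair of groups of 2 in which an exact permutation test cannot fall below a two-sided p of 0.333. Contig by contig, edgeR called 13 phased 24-nt contigs by daylength in NIL(MH) florets and 3 in its panicles of 1.0 to 2.0 cm. In 58S it called 16 in panicles of 0.5 to 1.0 cm and 3 in florets.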
